A study of Drosophila melanogaster with 3 samples.

How the data were processed

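Embryos of Drosophila melanogaster aged 0 to 20 h, of pooled sex, were analysed by chromatin immunoprecipitation and sequencing (ChIP-seq). They came from a transgenic line that carries the C2H2 zinc finger protein D19A with eGFP at its C-terminus. Per the labels, the immunoprecipitation used an antibody against GFP, although the antibody field of the labels names D19A itself, and the fragment size range was 200 to 800 bp. The 3 libraries are labelled as biological replicates 1, 2 and 3 of 1 group, so no comparison between groups was possible, and the comparisons were made within that group, between replicates, peaks, genes or sequences.

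The authors deposited 5 peak lists: 1 per library, 1 called on the 3 libraries pooled, and the optimal list that passed their irreproducible discovery rate (IDR) procedure, which compares the ranks of peaks between replicates. Per the labels and the record files deposited with the samples, coordinates are those of dm6, and all lists except the IDR list were derived from the library alignments and 1 control file that the 3 replicates share. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each replicate list and the pooled list hold exactly 30000 peaks, so their lengths carry no information on how much was bound. The value of each peak is the signal value the authors deposited, with no stated normalization. It was used only to rank peaks within its own list. The −log10 q-value the authors deposited reached a ceiling of 4.20 in the pooled list, at which 7866 peaks stood, the IDR peaks among them, and so could not rank the IDR peaks. The deposited summit offset gave the summit of each peak. It pointed outside the interval for 3 IDR peaks, which were kept. No read counts were among the deposited values, so the depth of each library is unknown, and intervals given for shares cover the counting of peaks only. The shared control file also means that part of any overlap between replicate lists may come from that control.

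The IDR list held 7769 peaks in 7581 distinct intervals, since 188 entries repeat an interval with another summit. Every entry was also in the pooled list, and together they were exactly the 7769 pooled peaks with the highest signal value. The 20127 pooled peaks that overlap no IDR peak served as the weaker comparison set. Sequence was taken from the RefSeq assembly with the same arms and lengths as dm6, and gene models from Ensembl release 115. The 5 long arms 2L, 2R, 3L, 3R and X and chromosome 4 were used, and annotated transposable elements were left out of the gene models. Transcription start sites (TSSs) were those of all annotated transcripts, 23581 positions in 18164 genes, of which 13945 are protein-coding.

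Overlap meant at least 1 shared bp. Random placement moved each interval to a uniform position on its own arm, 100 times, and 0.0099 is the smallest p that 100 placements can give (1-sided). A promoter peak had its summit within 250 bp of a TSS, and a gene was counted as carrying a promoter peak if any of its TSSs was that close to an IDR summit. Summits were assigned to promoter, 5′ UTR, coding exon, 3′ UTR, intron, other exon or intergenic sequence, in that order of precedence. Shares carry 95% Wilson intervals and peak densities exact 95% Poisson intervals. Densities per arm were tested with an exact 2-sided binomial test against the arm's share of length, gene lists and motifs with a 2-sided Fisher's exact test, each with Benjamini-Hochberg adjustment over its own family of 6 arms, 22 lists or 21 motifs. Odds ratios of lists and motifs were computed with 0.5 added to each cell. The background was all protein-coding genes for lists of symbols and all genes for RNA classes. The list fixed for long noncoding RNA genes took the ncRNA class of the annotation, which also holds miRNA precursors and their mature products as separate genes. Of the symbols in the lists, prs was not found in the annotation, and Clamp was listed under 2 spellings and counted once. A divergent promoter had a TSS of another gene on the opposite strand, head to head, within 500 bp upstream. For genes with a promoter peak this was judged at the TSS nearest to the summit, and for the others at their most 5′ TSS. The relation between peak rank and promoter status was tested with a permutation test of 100000 permutations.

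Sequence was compared between the 101 bp centred on each summit and a pair of 101 bp windows centred 200 bp to either side. All 8-mers, joined with their reverse complements, were tested on a random part of the IDR peaks (3881 peaks) and their odds ratios measured again on the remaining 3888, with peaks whose summits lie within 1000 bp of each other kept in the same part. The rank of a peak in a replicate is that of the highest-signal replicate peak that overlaps it, whose summit may lie elsewhere. The spread between replicates was obtained by repeating a measurement on the 7769 highest-signal peaks of each replicate list and is given as mean ± SD (n = 3).

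Named genes and peaks were fixed by rule before the data were examined: the genes nearest to the 15 IDR peaks of highest signal, up to 4 members with the highest-signal promoter peaks for each list past an adjusted p of 0.05 and up to 2 for each depleted list, the 3 strongest IDR peaks over 1 kb from every TSS, D19A and the other ZAD genes with a promoter peak, genes within 20 kb of D19A with an IDR peak, the 5 leading 8-mers and the motifs past the threshold. The gene lists, motifs and main tests, and alternatives for the overlap rule, the promoter window, the peak strength, the backgrounds and control windows, and each replicate left out, were fixed then too. Keeping only the strongest summit of each interval, the list of lncRNA and asRNA symbols, the AAGGGTAT word, the word at genomic positions matched on A and T content, the use of tRNA genes and of the pooled background as tests of an explanation, the position of summits relative to the TSS and the rank of list members were added after seeing the data.

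The procedures were tested on simulated data. For the 8-mer test on 32896 8-mers, 0 were called when nothing was planted, and 10 of 10 planted 8-mers were called. The simulated centres were shuffled flank windows with the composition of the flanks. This run therefore does not cover calls that arise from the higher A and T content of real summits. In 100 simulated gene list tests of 22 lists the raised list was called 99 times, and 0.286% of the other lists were called. For the overlap of 30000 peaks, 57.5% was measured where 57.8% was expected. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.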

Results

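ChIP-seq peaks of eGFP-tagged D19A were measured in 3 biological replicates of whole embryos aged 0 to 20 h. D19A is a zinc finger gene of the ZAD family on chromosome arm 3L, beside its paralogue D19B, and the labels give no other condition or genotype. The files hold peak positions and signal values, without read counts, so the depth of each library is unknown. Each replicate list holds 30000 peaks, and the IDR list made by the authors from the replicates and the pooled data holds 7769, with a median width of 444 bp. All coordinates are dm6. With 1 group, the comparisons the design allows are how far the replicates agree, where in the genome the peaks lie, which genes they mark and which sequences lie under them.

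The strongest peaks lay near a small set of genes and were the same in the 3 replicates. The IDR peak of highest signal (3R, 12448696 to 12449638, signal value 43197 as given by the authors) had its summit 128 bp from the TSS of CG18549, and ranked 1, 1 and 3 in replicates 1, 2 and 3. It was followed by peaks 213 bp from the TSS of Gbs-70E (3L, 14550592 to 14552197), which encodes a glycogen-binding regulator of a protein phosphatase, 75 bp from that of CG8067 (2R, 13982942 to 13984010) and 186 bp from that of osp (2L, 14689059 to 14689862). The peaks ranked 6 and 7 lay at phr, which encodes a photolyase that repairs light-damaged DNA, and pes, which encodes a scavenger receptor of the CD36 family. Those ranked 8 to 11 lay nearest to Phyhd1, the kinase gene Slik (143 bp from its TSS and inside Rpn8), lncRNA:CR45618 and aph-1, which encodes a subunit of γ-secretase. Peaks 13 and 14 lay 135 bp from a TSS of TP53INP and 211 bp from one of mthl5. Of these 15 peaks, 15 were among the top 15 of every replicate. Among the 500 strongest IDR peaks, 357 were among the top 500 of every replicate.

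The strongest peaks far from any TSS were as constant. The peak ranked 5 (3R, 23886142 to 23888507, 2366 bp wide) lay in an intron of Pli, which encodes Pellino, an adaptor of Toll signalling, 2849 bp from the nearest TSS, and ranked 4, 5 and 4 in the replicates. The peak ranked 12 (3L, 18280949 to 18281834) was intergenic, 12811 bp from the nearest TSS, that of CG5103. The peak ranked 15 (X, 2303680 to 2304533) lay in an intron of Raf, the kinase of the MAP kinase cascade, 8638 bp from the nearest TSS, and ranked 15 in each replicate. Such distal peaks were common, as 4058 IDR peaks (52.2%) had their summit over 1 kb from every TSS.

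Across whole lists, 75.2% to 80.4% of the peaks of a replicate overlapped a peak of another replicate, against a mean of 16.0% for random placements. The mean over the 6 ordered pairs was 78.0% ± 2.04 (SD), and each pair exceeded all 100 placements (permutation of positions, 1-sided p = 0.0099, the smallest that 100 placements can give). When overlap meant summits within 100 bp, the mean fell to 56.0%, against 4.56% for random placements. Of the 7769 IDR peaks, 5421 (69.8%, 95% interval 68.7% to 70.8%) were overlapped by a peak among the 7769 strongest of every replicate. The IDR list was itself selected from these libraries, so this count is a description with no test. The share of IDR peaks found among the 7769 strongest peaks of a replicate was 88.8% in replicate 1, 90.3% in replicate 2 and 81.3% in replicate 3 (86.8% ± 4.81, SD, n = 3). Because that limit equals the length of the IDR list, IDR peaks near the end of the ranking often fall beyond it, and 7513 IDR peaks (96.7%) were overlapped in the full lists of all 3 replicates. Overlap among equal numbers of the strongest peaks changed little with their number, with a mean over pairs of 86% for the top 100 and 80.3% for the top 7769. Overlap by random placement grows with the number of peaks, so these values do not show equal agreement beyond it. Across peaks matched through the pooled list, the Spearman correlation of signal values was 0.85 for replicates 1 and 2 (23617 peaks), 0.81 for 1 and 3 (22203 peaks) and 0.78 for 2 and 3 (22408 peaks). Among those that overlap an IDR peak it was 0.83, 0.84 and 0.71. These correlations are across peaks, which are not independent replicates.

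**Figure D1:**
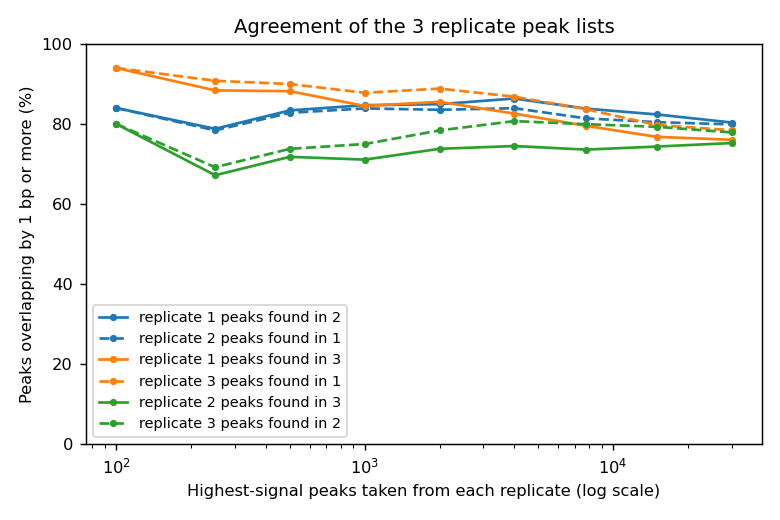
Share of a replicate's highest-signal peaks (y axis, %) that overlap a peak among as many of the highest-signal peaks of another replicate, against the number of peaks taken from each (x axis, log scale); each line is an ordered pair of replicates. Peaks of replicate 2 found in replicate 3 lie lowest from 250 peaks on, at 73.6% for 7769 peaks, and the 6 pairs lie between 75.2% and 80.4% at 30000 peaks. Overlap by random placement, which grows with the number of peaks, is not drawn.

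Relative to random placement, IDR summits were more frequent at promoters and in introns and rare in coding exons. Promoters held 2018 summits (26%, 95% interval 25% to 27%), 3.48 times the mean of 7.47% over random placements (permutation of positions, p = 0.0099), and the top lists of the single replicates gave 26.3% ± 2.13 (SD, n = 3). Introns held 3596 summits (46.3%, placements 39.0% to 42.2%) and intergenic sequence 1799 (23.2%, placements 27.1% to 29.6%). Coding exons held 26 summits (0.335%, 95% interval 0.228% to 0.490%), 46.6 times below the 15.6% of random placements, and the replicates gave 0.463% ± 0.123. The 3′ UTRs held 120 summits (1.54%, placements 4.16% to 5.53%), other exons 128 (1.65%, placements 0.927% to 1.48%) and 5′ UTRs 82 (1.06%, within the placements' 0.991% to 1.76%). The weaker pooled peaks outside the IDR set had fewer promoter summits (15.3%; odds ratio 1.95, 95% interval 1.83 to 2.08, Fisher's exact test p = 4.37e-91) and more summits in coding exons (1.75%; p = 5.06e-25) and introns (49.9%; p = 4.99e-08). Random placements were not kept out of repeated sequence.

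**Figure D2:**
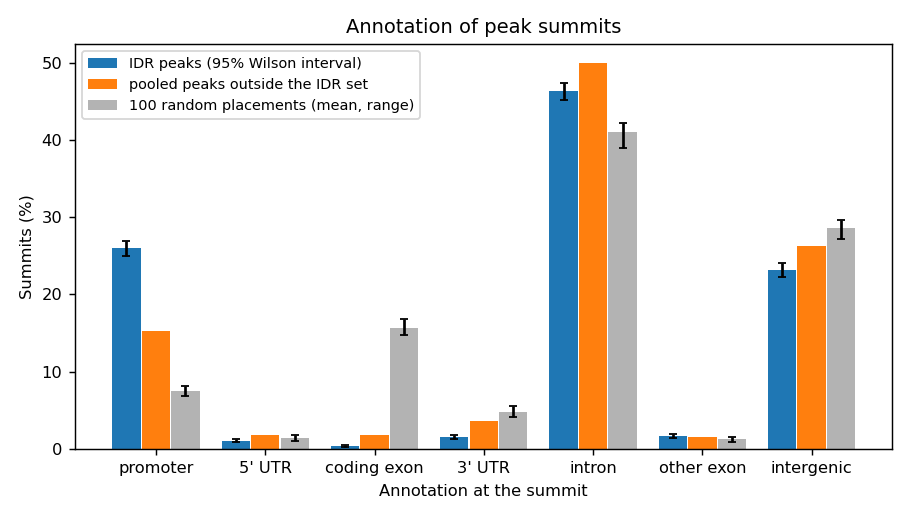
Percent of summits (y axis) in each annotation category (x axis) for the 7769 IDR peaks with 95% Wilson intervals, the 20127 pooled peaks outside the IDR set, and 100 random placements of the IDR peaks (mean, with the range as bars). Promoter summits make up 26%, 15.3% and 7.47%, and coding exon summits 0.335%, 1.75% and 15.6%.

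Promoter summits did not become more frequent with peak strength. The share was 27.5% for the 1943 strongest IDR peaks, 21.2% and 28.1% for the next groups of 1942 and 27.1% for the weakest, and rank and promoter status were not related within 250 bp (r = −0.01, permutation test p = 0.515). The 500 strongest peaks stood higher, at 34.8% (95% interval 30.8% to 39.1%). The relation depended on the window. Within 100 bp of a TSS, summits were rarer among stronger peaks (r = −0.11, p = 1e-05), and within 500 bp they were more frequent (r = 0.04, p = 0.00014).

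Head-to-head gene pairs were marked more often than other genes. Of the 2136 protein-coding genes with a promoter peak (15.3% of 13945), 955 had a divergent promoter (44.7%, 95% interval 42.6% to 46.8%), against 2938 of the 11809 others (24.9%; odds ratio 2.44, 95% interval 2.22 to 2.68, Fisher's exact test p = 2.02e-73). A summit between such a pair counts for both genes when it is within 250 bp of each, which raises this share. The test therefore treats linked genes as independent, and it compares TSSs chosen by different rules.

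Among the 22 gene lists, genes of cytoplasmic ribosomal proteins stood out. A promoter peak was present at 48 of 93 (51.6%), against 15.1% of other protein-coding genes (odds ratio 6.0, 95% interval 4.0 to 9.02, adjusted p = 3.27e-15 by Fisher's exact test), and the single replicates gave 44.3 ± 10.02 genes (SD, n = 3). The strongest were RpL37-1 (X, summit 173 bp from the TSS, rank 357), RpS21 (2L, 82 bp, rank 597), RpL34b (3R, 140 bp, rank 1151) and RpS27 (3R, 79 bp, rank 1777). Most of these peaks were of middle strength (median rank 3591). Only 5 of the 48 were among the 1942 strongest IDR peaks (10.4%, against 29.4% of other marked protein-coding genes; odds ratio 0.304, p = 0.00329 by Fisher's exact test), and restricted to those peaks the list no longer passed (odds ratio 1.34, adjusted p = 1.0). The odds ratio fell to 3.87 with the 5866 IDR peaks kept without replicate 2. It fell to 2.23 among genes with a pooled summit at the promoter, and rose to 10.5 with a window of 100 bp.

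Polycomb and Trithorax group genes, which keep developmental genes silent or active, were marked at 11 of 28 (39.3%; odds ratio 3.65, 95% interval 1.73 to 7.68, adjusted p = 0.00571; replicates 10.7 ± 3.79 genes, n = 3, Fisher's exact test). The paralogues ph-d (rank 48, summit 159 bp from the TSS) and ph-p (rank 140, 69 bp), both subunits of Polycomb repressive complex PRC1, the histone methyltransferase gene E(z) (rank 536, 103 bp) and the chromatin remodeller gene brm (rank 746, 126 bp) had the strongest peaks. The brm peak overlapped no peak of replicate 3, and ranked 838 and 484 in replicates 1 and 2. Mitochondrial ribosomal protein genes were marked at 20 of 73 (27.4%; odds ratio 2.13, 95% interval 1.28 to 3.55, adjusted p = 0.0198 by Fisher's exact test), led by mRpS10 (rank 104), mRpL41 (rank 208), mRpL23 (rank 386) and mRpL24 (rank 552). Signalling ligands and receptors were marked at 11 of 32 (34.4%; odds ratio 2.97, 95% interval 1.45 to 6.08, adjusted p = 0.0167 by Fisher's exact test), led by spi (rank 643), an EGF receptor ligand, arr (rank 3709), a Wingless co-receptor, vn (rank 4412), another EGF receptor ligand, and Delta (rank 4566), a Notch ligand. The calls of these last 3 lists depended on the setting. When the background was only the genes with a pooled summit at the promoter, none of the 3 passed Fisher's exact test, with odds ratios of 2.62 for the Polycomb and Trithorax genes, 1.68 for the mitochondrial ribosomal proteins and 0.939 for the signalling genes (adjusted p = 0.324, 0.495 and 1.0). With IDR peaks supported by every replicate the odds ratios were 3.07, 2.15 and 1.75 (exact test, adjusted p = 0.0552, 0.0552 and 0.629). With the 5866 IDR peaks kept without replicate 2 they were 2.92, 2.04 and 2.91 (exact test, adjusted p = 0.0608, 0.0735 and 0.0533). Without replicate 1 the mitochondrial ribosomal proteins (2.12) and signalling genes (1.6) did not pass the exact test (adjusted p = 0.0622 and 0.622), nor did the signalling genes without replicate 3 (2.09, adjusted p = 0.235). Among the 3884 strongest peaks the signalling genes stood at 0.966. Cytoplasmic ribosomal protein genes passed the exact test with the pooled background (adjusted p = 0.00854) and with support by every replicate (1.7e-07).

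Chemoreceptor, cuticle protein, snoRNA and histone genes, and the genes annotated as ncRNA, were marked less often than other genes. None of 179 chemoreceptor genes carried a promoter peak (adjusted p = 1.34e-12 by Fisher's exact test), and 1 of 117 cuticle protein genes did, Cpr65Ea (rank 4515; odds ratio 0.0705, or 0.107 without replicate 2, adjusted p = 6.42e-07). In the chemoreceptor and cuticle lists 2 and 2 genes had a pooled summit at the promoter at all. Genes of the annotation's ncRNA class, chosen to represent long noncoding RNAs, were marked at 179 of 3261 (5.49%, against 14.7% of other genes; odds ratio 0.339, adjusted p = 7.39e-52 by Fisher's exact test). That class also holds 741 miRNA precursors and mature products, listed as separate genes, of which 20 were marked. Genes with lncRNA or asRNA symbols alone, a list made after the data were seen, were marked at 153 of 2447 (6.25%; odds ratio 0.389, 95% interval 0.328 to 0.461, adjusted p = 5.27e-33 by Fisher's exact test), with lncRNA:CR34335 (rank 19) and asRNA:CR45999 (rank 82) the strongest. Genes of snoRNAs, most of which are processed from introns of host genes, were marked at 5 of 269 (1.86%; odds ratio 0.137, adjusted p = 3.31e-10 by Fisher's exact test), including snoRNA:185 (rank 2476) and snoRNA:Me18S-A1576 (rank 3125). None of the 111 replication-dependent histone genes was marked (adjusted p = 6.3e-08 by Fisher's exact test), and none had a pooled summit either. These genes lie in a tandem repeat, so the test treats linked copies as independent. Reads may not be placed uniquely there, which could not be checked with these files.

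The other 13 lists did not pass the threshold. Insulator and architectural protein genes were marked at 7 of 21 and translation factor and tRNA synthetase genes at 20 of 83 (adjusted p = 0.0638 for each by Fisher's exact test), and heat shock genes at 5 of 16 (adjusted p = 0.156). Proteasome genes were marked at 10 of 48, oxidative phosphorylation genes at 16 of 80, replication and cell cycle genes at 8 of 34, snRNA genes at 6 of 32, tRNA genes at 32 of 290, gap, pair-rule and segment polarity genes at 6 of 29, muscle structural protein genes at 3 of 20, neuronal differentiation genes at 2 of 18 and Hox genes at 1 of 8. The tRNA genes (odds ratio 0.837) were marked less often than other genes by Fisher's exact test among the 3884 strongest peaks (odds ratio 0.423, adjusted p = 0.0154), among the 1942 strongest (0.223, adjusted p = 0.0107) and among genes with a pooled summit at the promoter (0.364, adjusted p = 1.85e-06). Some neighbouring tRNA genes share a summit, such as tRNA:Leu-CAG-1-3 and tRNA:Leu-CAG-1-2 (rank 4166), so the tests treat linked genes as independent. ZAD zinc finger genes, the family of D19A, were marked at 3 of 23 (odds ratio 0.943, 95% interval 0.303 to 2.93, adjusted p = 1.0 by Fisher's exact test), namely D19A (rank 1535), pad (rank 5815) and hang (rank 6356). The paralogue D19B was not counted as marked, since the IDR summit upstream of it lay just beyond the promoter window.

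**Figure D3:**
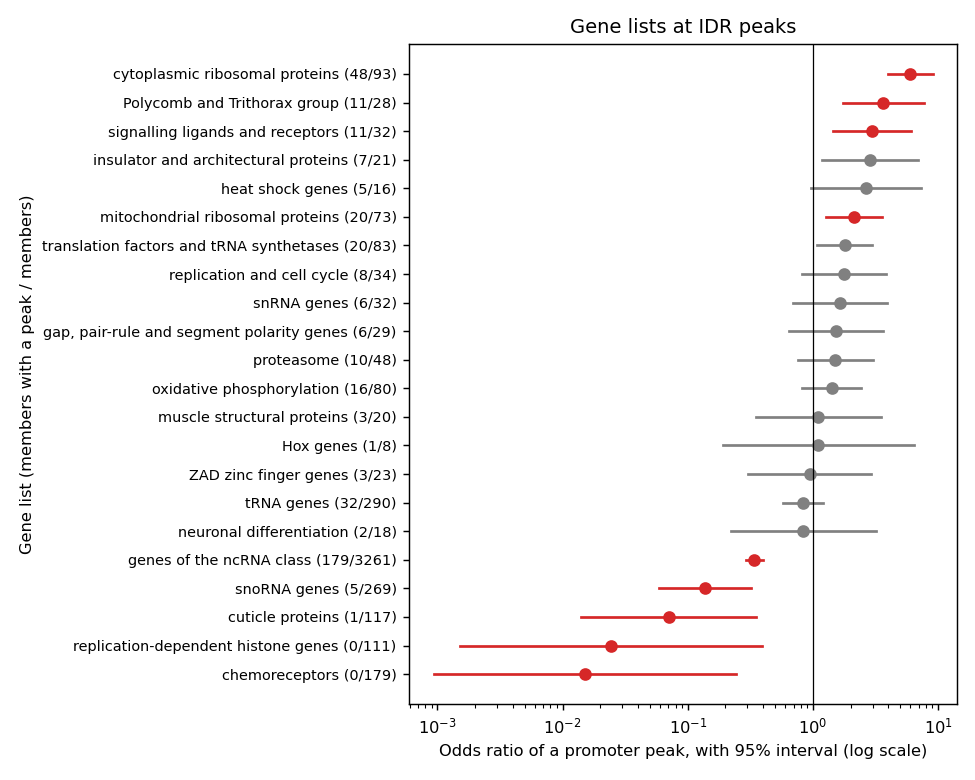
Odds ratio of carrying an IDR promoter peak (x axis, log scale) with its 95% interval for each of the 22 gene lists (y axis, with members marked and members in the list), against the other genes of the background; red marks an adjusted p under 0.05. Cytoplasmic ribosomal protein genes have the highest odds ratio, 6.0, and chemoreceptor genes, none of them marked, the lowest.

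Density differed among the arms. It was 62.9 peaks per Mb on 3L (95% interval 60.03 to 65.9) and 61.8 on 2L (58.6 to 65.0), above the share of length (adjusted p = 0.000429 and 0.0114, exact binomial test), and 54.3 on 3R and 52.8 on 2R, below it (adjusted p = 0.00234 and 0.000429). X held 57.7 per Mb (adjusted p = 0.846, exact binomial test). The small chromosome 4, which is largely heterochromatic, held the densest set, with 110 peaks and 81.6 per Mb (95% interval 67.1 to 98.3, adjusted p = 0.00125, exact binomial test), but the replicates differed there, at 84.6 ± 18.5 per Mb (SD, n = 3). With the 6310 IDR peaks kept without replicate 3, chromosome 4 and 3R no longer passed the exact test (adjusted p = 0.0519 for each). Set against the weaker pooled peaks instead of length, chromosome 4 held 0.758 times its expected share of IDR peaks (adjusted p = 0.00507, exact test) and 3R 1.12 times (adjusted p = 7.46e-07), the opposite direction for both, and X held 0.865 times its expected share (adjusted p = 8.02e-09). Among the 1942 strongest peaks no arm differed from its share of length past the threshold.

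Sequence under the summits was rich in A and T. The windows centred on IDR summits held 67.5% A or T, against 57.7% in the flanking windows and 57.8% at randomly placed positions, and the replicates gave 66.9% ± 0.882 (SD, n = 3). The share rose with peak strength, from 62.4% in pooled peaks outside the IDR set and 65.0% in the 1942 weakest IDR peaks to 70.4% in the 1943 strongest. Of 32889 8-mers tested, 1285 were more frequent at summits than in flanks and 816 less frequent (adjusted p under 0.05, Fisher's exact test), and of the 1285, 1264 were also more frequent in the remaining peaks. The 5 leading 8-mers held only A and T. AAATATAT occurred in 7.46% of the remaining summits and 2.51% of flanks (odds ratio 3.13, p = 4.17e-34, Fisher's exact test), and ATATTTTA, ATATTTAA, AATAATAT and ATTTAAAA had odds ratios of 3.19, 2.94, 3.63 and 2.49 there. When summit sequences shuffled with their dinucleotides kept were the control, 89 8-mers were more frequent, and the odds ratios of the 5 leading 8-mers in the remaining peaks were lower. They were 2.52 for AAATATAT, 1.74 for ATATTTTA, 1.49 for ATATTTAA, 1.47 for AATAATAT and 1.15 for ATTTAAAA, which no longer passed (p = 0.156, Fisher's exact test). In the peaks used for the search, AATAATAT and ATTTAAAA did not pass against shuffled sequence (adjusted p = 0.901 and 0.136, Fisher's exact test). By the same exact test, the lowest p against these shuffled sequences belonged to AAGGGTAT, a word singled out after its values were seen. It occurred in 3.01% of the remaining summits, 0.862% of their flanks (odds ratio 3.56, p = 3.84e-17, Fisher's exact test) and 0.386% of shuffled sequences. Against summits outside the IDR set its odds ratio in the remaining peaks was 2.88 (p = 1.23e-14, Fisher's exact test). AATACCCT and ATACCCTA, read on the other strand, share AGGGTAT with it. In the remaining peaks they too were more frequent than in shuffled sequence (odds ratios 6.92 and 8.45). Peaks with any of these words were not counted together. Over all IDR peaks AAGGGTAT was found at 238 summits (3.06%; replicates 3.1% ± 0.481, n = 3), and the 1943 strongest held it more often (4.58%, 95% interval 3.74% to 5.60%) than the 1942 weakest (2.01%, 95% interval 1.47% to 2.73%). Promoter summits held it less often (1.54%, 95% interval 1.08% to 2.17%) than other summits (3.6%, 95% interval 3.15% to 4.11%).

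**Figure D4:**
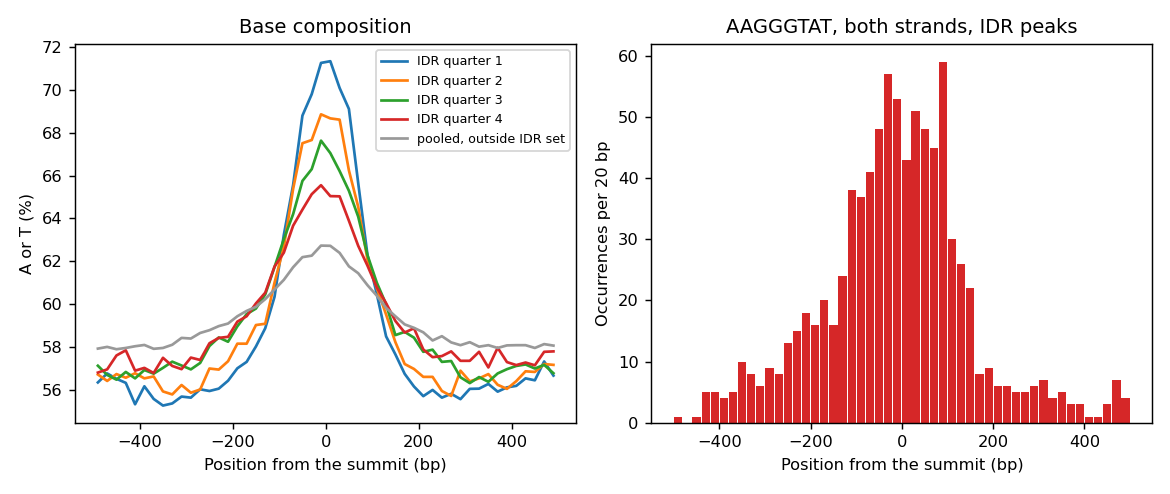
Left, percent A or T (y axis) in 20 bp steps against the position from the summit in bp (x axis), for the IDR peaks in 4 groups by rank (1 the strongest) and the pooled peaks outside the IDR set; right, occurrences of AAGGGTAT on either strand (y axis, per 20 bp) around IDR summits (x axis, bp). The A or T share in the summit window is 70.4% in the strongest group and 62.4% outside the IDR set. The word forms a broad plateau around the summit without a sharp maximum there, with 37 occurrences at −90 bp, 57 at −30 bp, 53 at −10 bp, 43 at 10 bp and 59 at 90 bp. Further away it falls, to 9 at −290 bp and 6 at 290 bp.

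Of 21 known motifs written before the data were examined, 10 differed from the flanks. The TATA box (TATAAA) was found at 25.6% of summits and 12.3% of flanks (odds ratio 2.45, adjusted p = 1.4e-136), and the Ibf motif at 0.245% and 0.0965% (odds ratio 2.52, adjusted p = 0.0222), by Fisher's exact test. Ibf did not pass the exact test without replicate 1 or 2 (adjusted p = 0.3 and 0.12), nor Pho without replicate 2 (adjusted p = 0.0628). The other 8 were rarer at summits. Binding words of the GAGA factor (odds ratio 0.348, adjusted p = 6.52e-27, Fisher's exact test) and CLAMP (odds ratio 0.334, adjusted p = 4.63e-14), which recognise GA repeats, were depleted, as were the E-box CAGCTG (odds ratio 0.523), the TAGteam-like word (odds ratio 0.537), the Twist and Snail word (odds ratio 0.595), Grainyhead (odds ratio 0.161 from 3 peaks, and 0.0921 to 0.0981 with a replicate left out), Motif 7 (odds ratio 0.748) and Pho (odds ratio 0.796). The CLAMP word contains the GAGA factor word, so the results for GAGA factor and CLAMP are not separate, whatever the control. The directions depended on the control. Against shuffled summit sequence, the TATA box no longer passed (odds ratio 1.08, adjusted p = 0.0602, Fisher's exact test), and GAGA factor, CLAMP and E-box words were more frequent than in the shuffled control (odds ratios 2.60, 8.50 and 2.37). Against summits outside the IDR set the directions of these motifs were those found against the flanks, with odds ratios of 1.48 for the TATA box, 0.665 for GAGA factor, 0.627 for CLAMP and 0.674 for the E-box (adjusted p = 1.65e-33, 0.000991, 0.0122 and 4.86e-06, Fisher's exact test). Motif 7 turned there, to 1.11, and did not pass (adjusted p = 0.603, Fisher's exact test). The word bound by DREF and that bound by M1BP did not pass against the flanks (odds ratios 1.18 and 0.829), nor did ZIPIC (odds ratio 1.03). Against the shuffled control all 3 were more frequent, with odds ratios of 4.06, 3.93 and 15.04 (adjusted p = 2.22e-06, 0.00228 and 2.37e-05, Fisher's exact test).

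The tagged gene was itself among the marked genes. The tagged transgene may add copies of this locus, so a peak here need not reflect binding at the native promoter. D19A (3L, 6185830 to 6189123, minus strand) had an IDR peak at its promoter (6189085 to 6189414, rank 1535), with the summit 174 bp from the TSS. The peaks that overlapped it in replicates 1 and 2 ranked 1341 and 1457, with summits at 6189339 and 6189292. In replicate 3 the overlapping peak (rank 2414) had its summit at 6189477, beyond the promoter window of D19A and next to the CG7386 summit of the IDR list at 6189498. A further summit of rank 3448 lay 247 bp from the TSS of the neighbouring gene CG7386, which is on the opposite strand. On the other side, CG43293, beside the 3′ end of D19A, held 2 summits in 1 interval (6184981 to 6185401), ranked 468 and 4532. The stronger, at 6185175, also lay upstream of the paralogue D19B (6182176 to 6184920, minus strand), just beyond its promoter window. In replicate 2 the corresponding summit, at 6185152, fell inside that window. In replicates 1 and 3 those at 6185176 and 6185180 did not. The gene fmt held a summit 84 bp from its TSS (rank 1198). The 5 IDR summits within 20 kb of D19A did not exceed random windows of the same size on 3L, which held 2.87 on average (p = 0.253, permutation of 1000 windows, 1-sided). The pooled list held the same number there, 5, against 10.9 in random windows.

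**Figure D5:**
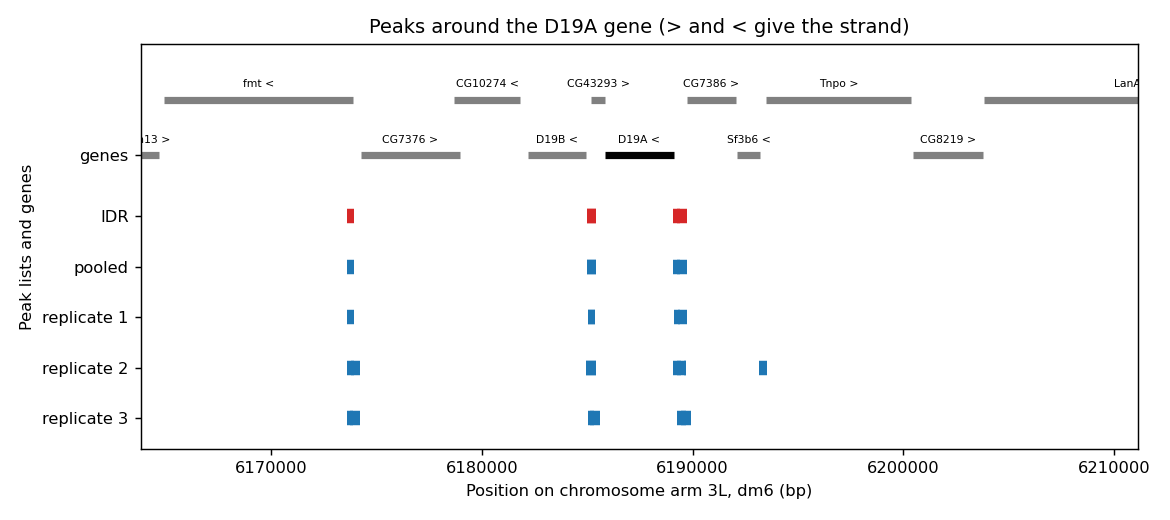
Peaks of the 5 lists (bars in the lower rows) and annotated genes (upper rows, D19A in black, > and < for the strand) against the position on 3L in dm6 (x axis, bp), within 22 kb of D19A. IDR peaks lie at both ends of D19A and at fmt.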

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

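Keeping the strongest summit of each interval and restricting the ncRNA class to lncRNA and asRNA symbols were chosen after seeing the data; the first moved no summary value past its threshold or spread, and with the second the list still passed (odds ratio 0.389). Of the summary values recomputed under the alternatives, 81 kept their direction and side of the threshold or moved little, 13 moved further, 2 turned direction and 1 passed the threshold only under the alternative. Of the values for single arms, lists, words and motifs 586 kept theirs, 54 fell short of the threshold, 20 passed it only under the alternative and 20 turned direction. No read counts were used, so how depth limits these values could not be measured. With the N/2 strongest peaks of each replicate in place of 7769, 3020 IDR peaks were shared by all, a fall set by the shorter lists, and leaving out a replicate gave 5725 to 6310. The rank correlation lay between 0.78 and 0.85 with a replicate left out. Except for the size of the peak sets and lists, the cause of the changes below was not tested. The number of arms past the threshold, 5, became 2 with the 3884 strongest peaks, 0 with the 1942 strongest, 3 against the pooled peaks outside the IDR set, and 3 to 5 with a replicate left out. Against those pooled peaks the ratio turned to 1.0 for 2R, 1.12 for 3R and 0.758 for chromosome 4, which was also at 0.972 among the 1942 strongest. The correlation of rank and promoter status was −0.11 within 100 bp, 0.0432 within 500 bp and 0.0561 within 1000 bp. The number of gene lists past the threshold, 9, became 4 among genes with a pooled summit at the promoter, a test of fewer genes, where the odds ratio turned to 0.939 for signalling genes and to 1.02 for the cuticle and 1.02 for the histone lists, which then hold 2 and 0 genes. Signalling genes were also at 0.966 among the 3884 strongest peaks, and mitochondrial ribosomal protein genes at 0.858 with a window of 100 bp. The 1285 8-mers more frequent at summits became 452 among the 1942 strongest peaks, 89 against shuffled sequence, 219 against summits outside the IDR set, 451 for 6-mers, which are fewer, and 56 for promoter peaks alone. The number of motifs past the threshold, 10, became 5 for promoter peaks alone. Against shuffled sequence, which keeps the composition of the summit, among motifs past the threshold with either control, the odds ratio turned above 1 for M1BP (3.93), GAGA factor (2.60), CTCF (1.75), E-box (2.37), Initiator (1.14), Motif 7 (1.93), the TAGteam-like word (1.15) and CLAMP (8.50), and was 1.0 for Grainyhead. Motif 7 was also at 1.11 against summits outside the IDR set and 1.05 for promoter peaks alone. Around D19A, 4, 5 and 10 summits in windows of 10, 20 and 50 kb did not pass, and the pooled list fell below the random mean.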

Other observations

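The position of promoter summits and the rank of ribosomal protein peaks were examined only after the data had been seen; the tRNA list and the pooled background were planned, but their use as tests of background, and the word at positions matched on A and T content, were chosen after. Among the 2801 IDR peaks with a summit within 500 bp of a TSS, 2112 had it upstream of the nearest TSS (75.4%, 95% interval 73.8% to 77.0%), at a median of 131 bp upstream. The stronger the peak, the further upstream the summit lay. The median was 172 bp upstream for the strongest rank group (83.3% upstream), 143 and 102 bp for the next groups, and 75.5 bp for the weakest (68.0% upstream), with a Spearman correlation of −0.20 between signal and position (permutation p = 0.0001, the smallest that 10000 permutations can give). The trend was present at TSSs with no opposite-strand TSS within 500 bp (2051 peaks, −0.21, permutation p = 0.0001), with medians of 203 bp for the strongest group and 85.5 bp for the weakest. At the 48 cytoplasmic ribosomal protein genes with a summit within 250 bp of a TSS, the median was 37 bp upstream. Marked tRNA genes, like the ribosomal protein genes, were seldom among the 1942 strongest peaks (2 of 32, against 28.6% of other marked genes; p = 0.00457, Fisher's exact test). Some of these tRNA genes share a summit, so they are not independent in this test.

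No biological explanation could be tested, since the design has a single group, and a first hypothesis is that the word AAGGGTAT is a sequence feature of D19A-eGFP binding rather than a by-product of A and T content or of repeats. If A and T content alone were behind the word, genomic positions outside coding exons matched on arm and on A and T content should hold it as often as the remaining peaks, but 0.427% did (0.129% to 0.694% over 100 draws) against 3.01% (95% interval 2.52% to 3.59%). The odds ratio of 7.79 against shuffled summit sequence (95% interval 4.58 to 13.2) does not bear on this, since the word was picked with that control and motifs rarer at summits than in flanks exceed it too. Outside annotated transposable elements (7559 peaks) the odds ratio against flanks was 3.81 (95% interval 3.03 to 4.79). The word stood at 2.82% of these summits, against 3.06% of all IDR summits. The 210 peaks near an element therefore held it more often than the rest. They are too few to move the odds ratio much, so this shows only that the word is not confined to them. The transposable element test and the next also used the peaks in which the word was picked. Against flanks, its odds ratio was 4.75 in those peaks and 3.56 in the remaining ones. Among peaks with no soft-masked base within 250 bp, the word had an odds ratio of 6.32 (95% interval 1.48 to 26.9) and the centre exceeded the flanks by a median of 8.42 percentage points of A and T (95% bootstrap interval 3.96 to 9.9), although these were only 115 of 7769 peaks (1.48%), so for most peaks the part of low-complexity sequence stays open. Whether the word reflects D19A itself, another protein at the same sites or the antibody could not be examined without a GFP-only sample. Most peaks, including 14 of the 15 strongest, lack this exact 8-mer, though peaks with only an overlapping word were not counted. Occurrences of AAGGGTAT formed a broad plateau around summits, fell further away and had no sharp maximum at the summit itself.

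The scarcity of coding exon summits may come partly from base composition, as coding exons are poor in A and T. Random positions matched to the peaks on arm and A and T content fell in coding exons in 5.04% of cases (4.56% to 5.62% over 100 draws), compared with 16.2% of unmatched positions, drawn in equal number from each arm, and 0.335% of IDR summits (95% interval 0.228% to 0.490%). Matching on composition thus lowered the share in coding exons, and the summits remained below the matched positions. The test cannot show that composition is a cause. Peaks kept out of coding exons for another reason would also be rich in A and T. Accessible chromatin outside coding sequence is an open explanation that these files do not address.

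The ribosomal protein promoters are a candidate for a technical origin, because strongly transcribed genes can gather background in ChIP. Genes matched on upstream A and T content carried a promoter peak in 16.5% of cases (7.53% to 29.0% over 100 draws), below the 51.6% of ribosomal protein genes (95% interval 41.6% to 61.5%). Background shared by strongly transcribed genes of any polymerase stays open: tRNA genes were not raised among IDR peaks (odds ratio 0.837, 95% interval 0.580 to 1.21), but in the pooled list, where weak background would show, 131 of 290 had a promoter summit (45.2%, against 27.6% of other genes; odds ratio 2.16, 95% interval 1.71 to 2.73), and fewer of those than of other genes with a pooled summit had an IDR summit (24.4% against 47.3%; odds ratio 0.364, adjusted p = 1.85e-06 by Fisher's exact test). Neighbouring tRNA genes can share a summit, so they are not independent in these tests. Among genes with a pooled summit at the promoter, the ribosomal protein genes differed in the direction opposite to the tRNA genes, with an odds ratio of 2.23 (95% interval 1.35 to 3.69). The IDR peaks are the pooled peaks of highest signal. The ratio therefore shows only that ribosomal protein promoters with a pooled summit more often held a stronger one. Background that rises with transcription could give the same result, so the test does not count against it. Background specific to RNA polymerase II and sites bound through another protein were not tested: the peaks are mostly of middle rank, and no expression data or mock immunoprecipitation was analysed here.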
